A study of Vitis vinifera with 2 samples.

How the data were processed

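DNA affinity purification sequencing (DAP-seq) was carried out in vitro: fragmented, adapter-ligated genomic DNA was mixed with a transcription factor made in rabbit reticulocyte lysate and held on beads by a HALO tag, and the bound fragments were eluted, amplified and sequenced, per the labels' protocols. The DNA came from young leaves of 'Cabernet Sauvignon' clone 08. There were 2 groups of 1 library each: HALO-tagged grapevine MYB24, and the HALO tag alone (pIXHALO), which served as the negative control. The assay uses naked DNA, so chromatin does not enter the measurement.

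Reads were trimmed with Trim Galore 0.6.6 and cutadapt 3.1 and aligned with Bowtie2 2.3.2, per the submitters' processing notes. Binding events were called with GEM, per the names of the deposited lists. The alignment settings, the treatment of reads with several equally good positions, the GEM version and its settings are not given in the sources used here. The authors deposited 2 event lists for the MYB24 library and none for the control was analysed here. Sequence names in both lists are those of the Cabernet Sauvignon clone 08 assembly, version 1.1, in which each primary contig carries one version of a locus and haplotigs carry the alternative version of parts of it. One list has events on primary contigs only (the primary-only list), and the other has events on primary contigs and haplotigs (the diploid list). That the first was made by aligning to the primary contigs alone is read from its sequence names.

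The lists have no header, and their columns were read in narrowPeak order. Each event is an interval of 201 bp with the event at an offset of 100 bp. The deposited signal of each event is called its strength here. It was at most 1315 in both lists and was deposited with 1 decimal, which was 0 for 69.0% of the primary-only events, and what it counts is not given in the sources used here, so depth and counting error of single events are unknown. The deposited score was a straight-line function of strength, to within 0.561 score units, and was capped at 1000, so it was not analysed further. The deposited −log10 p-value and −log10 q-value of each event were the authors'. The smallest −log10 q in each list was 2, which is a q of 0.01. All of these values belong to single events of 1 library, and they were used to describe, rank and filter events within a list. Strengths were also set beside those of the other list without a test. This was done for the strongest events, for medians and for the smallest primary-only strength. Only strengths of matched cluster events on 2 contigs were tested between the lists, in the closing section, since both lists come from the same library. Whether strength is scaled alike in both is not given in the sources used here. Positions are the event positions that the authors wrote in the event names, which can differ by 1 bp from the 1-based position, and start and end of an interval are given 1-based.

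Events of the lists were matched on primary contigs where they lay within 100 bp of each other. The chance level of matching came from 100 random placements of the primary-only events between the first and last event of their contig, since contig lengths were not at hand. Clusters were runs of at least 5 events with neighbours up to 5 kb apart, and their chance number came from 1000 such placements. Periodicity was measured on distances of up to 1 kb between neighbouring events. The resultant length (0 for no common period, 1 for exact multiples) was computed for every period from 10 to 150 bp, and its largest value was compared with that of distances jittered by up to 50 bp either way, 10000 times, so the p-value covers all periods tried but not the choice of the clusters. The share of distances within 2 bp of a multiple of the period found was compared with 100000 such jitters. Tests of spacing and of neighbouring status were one-sided, toward higher values, and those of differences two-sided. Log2 strength ratios of matched cluster events were tested with exact sign tests, which treat neighbouring events as independent. Other tests were permutation tests with 100000 resamples, or 10000 for the comparison of −log10 p at equal strength. Intervals on shares are 95% Wilson intervals, and they treat events as independent and cover counting error only.

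Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data at the size of the primary-only list. Among 6663 events 100.0% of planted counterparts were recovered, and 1.86% of the other events were called matched. The clusters found rose from 5 among randomly placed events to 25 after 20 were planted. Counterparts were planted within the matching distance and clusters within the linking distance, so their recovery was largely fixed in advance and checks the code only. A period of 37 bp planted in 40 distances was found. Without a period, 8 of 100 simulations of 40 distances passed p of 0.05.

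No sequence or gene models of this assembly were used here. The planned tests of MYB motifs at events, of event position relative to genes and of the fixed gene lists (terpene synthases, flavonol and other phenylpropanoid enzymes, light signalling, carotenoid and jasmonate genes among them) were therefore not run, and no gene is named from an event. The table of grapevine gene names at hand belongs to an assembly of another cultivar, Pinot Noir, and was not used. Before the data were examined, the named items in this case were fixed as the 10 strongest events of the list with more events, which was the primary-only list. That plan also fixed the matching distance and the q thresholds. The clusters, the periodicity and their alternatives, the comparison of strength with −log10 p, and every other contig or event named were chosen after their values were seen. With 1 library per group there is no replicate, so no p-value here measures the spread between libraries.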

Results

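Binding of grapevine MYB24 to naked 'Cabernet Sauvignon' leaf DNA was recorded in 1 library and compared by the authors with 1 library made with the HALO tag alone, per the series' design text. MYB24 is an R2R3-MYB transcription factor, and the series asks which loci it binds in relation to terpene and flavonol metabolism in berries. The deposited primary-only list had 6663 events on 427 primary contigs. The diploid list had 6102 events on 851 sequences, of which 4042 lay on 427 primary contigs and 2060, or 33.8% (95% interval 32.6 to 34.96%), on 424 haplotigs. A haplotig is an assembled stretch of the alternative haplotype of the heterozygous vine. Read depth is unknown, since the lists give events and not libraries, and events of the control were not analysed here.

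Most MYB24 events had a low strength, and a few had a strength far above the rest. In the primary-only list the median strength was 46, with quartiles of 35.5 and 68.0, while the strongest event reached 1315. Strength was over 100 at 810 events and over 300 at 83. The median −log10 q was 4.82, 3205 events (48.1%) reached 5 and 1541 (23.1%) reached 10. In the diploid list the median strength was 28.0, 327 events were over 100, 22 were over 300, and 2012 events (32.97%) reached a −log10 q of 5. Its haplotig events had a median strength of 26.8 and those on primary contigs 29.0. The smallest strength in the lists was 23 for primary-only and 13 for diploid, at the same q limit. The strongest 1% of events held 7.20% of the summed strength in the primary-only list.

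The strongest event lay on Primary000101F at position 358281 (interval 358182 to 358382), with a strength of 1315 and a −log10 q of 181. It had the same strength in the diploid list. The next was on Primary000008F at 3582861 (3582762 to 3582962), with a strength of 760.0 and a −log10 q of 190, but in the diploid list the event 1 bp away had a strength of 66.0. An event on Primary000106F at 1791106 (1791007 to 1791207) had the highest −log10 q of the list, 198, with a strength of 754.6, and the diploid list had no event within 35249 bp of it. The event on Primary000021F at 1425506, with a strength of 551.0, had no counterpart either. On Primary000280F at 299890 and Primary000273F at 2619, strengths of 749.3 and 565.7 in the primary-only list stood beside 788.7 and 547.0 in the diploid list. Primary000061F at 390066 had 550.0 against 390.0, and Primary000147F at 602619 had 546.0 against 129.0. Primary000002F at 7233645 had 639.6, and the nearest diploid event, 77 bp away, had 34 and can be another site. On Primary000033F at 1024416 the strength was 648.5 in the primary-only list and 806.0 in the diploid list. In all, 8 of the 10 strongest events had a counterpart within 100 bp. On the haplotigs, the strongest event was on Haplotig000049F_003 at 46118, with a strength of 435.0 and a −log10 q of 107.

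Strength and significance over the control parted at a few of these loci. The median −log10 p per unit of strength was 0.250 over the 83 primary-only events with a strength over 300, and 5 of them were under 0.1. These were the 2 events on Primary000273F, at 2619 and 2674, and those on Primary000033F at 1024416, Primary000054F at 448605 and Primary000280F at 299890. The event at 2674 on Primary000273F had a strength of 374.3 and a −log10 q of 5.29, the lowest value per unit of strength in this group. In the diploid list 6 of 22 such events were under 0.1, namely a counterpart of each of these 5 and Haplotig000015F_018 at 296974. No replicate was at hand to give the spread of these values.

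The lists with and without haplotigs differed in which MYB24 events they held. Of the 6663 primary-only events, 2929 or 43.96% (42.8 to 45.1%) had a diploid counterpart on the same primary contig within 100 bp, and 3734 had none. Random placement gave 1.26% on average and 1.40% at most. An event alone on its contig kept its own position in every placement, which can raise these values above chance. In the other direction, 2928 of 4042 diploid events on primary contigs, or 72.4% (71.0 to 73.8%), had a primary-only counterpart. Of the 1114 that had none, 808 (72.5%) had a strength under the smallest of the primary-only list. Both lists come from the same library, so these shares do not measure the spread between libraries.

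The share of events found in both lists did not rise steadily with strength. Over 5 groups of nearly equal size, from the weakest to the strongest events, it was 52.5% (49.8 to 55.2%), 30.4% (28.0 to 32.9%), 35.6% (33.1 to 38.2%), 41.3% (38.7 to 43.96%) and 59.9% (57.3 to 62.5%). Matched events had a median −log10 q of 6.46 in the primary-only list and unmatched events 3.96, with median strengths of 48.4 and 44. Among the diploid events on primary contigs, the median strength was 35 for matched and 20 for unmatched events.

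**Figure D1:**
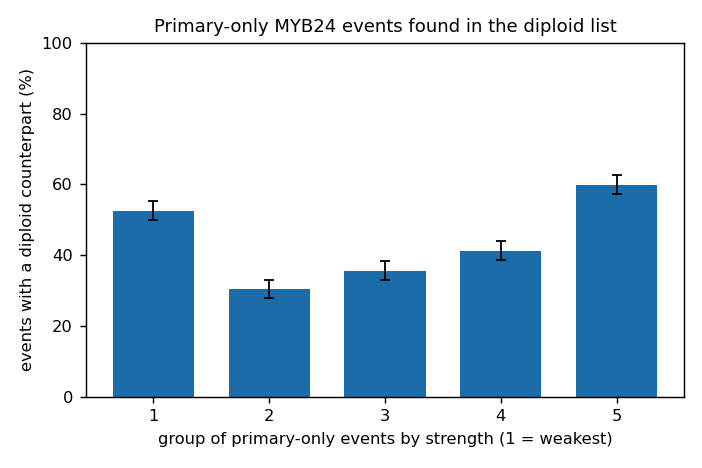
Share of primary-only MYB24 events (%, bars from 0) with a diploid counterpart within 100 bp on the same primary contig, in 5 groups by event strength, with 95% Wilson intervals. The share was lowest, 30.4%, in group 2 and highest, 59.9%, in group 5, the strongest events.

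MYB24 events were unevenly spread along the contigs. Neighbouring primary-only events lay a median of 37990 bp apart, and 545 of 6236 neighbouring distances (8.74%) were within 1 kb, against a mean of 128 and a highest value of 165 in 1000 random placements. There were 18 clusters of at least 5 events with 140 events on 15 contigs, against a mean of 3.05 and a highest value of 7 in the random placements. All 10 events of Primary000502F lay in 1 cluster of 9078 bp. Placement between the first and last event tends to give that cluster again, so it was not tested by these placements. Over the 158 contigs with at least 10 events, the median density between first and last event was 15.8 events per Mb.

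The stretches with most events were on Primary000106F and Primary000033F. Primary000106F had 36 of its 46 events (78.3%) within 53.9 kb, from 1497536 to 1551460, in clusters of 12, 8 and 16 events. The median strength of these 36 events was 129, above the upper quartile of the list, and the strongest, at 1508390, had 539.0. Primary000033F had 19 events within 17.0 kb, from 1821194 to 1838220, with a median strength of 53.9 and the strongest, at 1835700, at 371.9. Smaller clusters included 10 events on Primary000502F from 117094 to 126171, 8 on Primary000081F from 372467 to 380285, and 7 each on Primary000009F from 1664198 to 1668592 and on Primary000159F from 642003 to 647854.

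These stretches were also dense in the diploid list. On Primary000033F, 18 of the 19 cluster events (94.7%, 75.4 to 99.1%) had a counterpart, and the diploid list had 21 events in the stretch, with a median strength of 44.2. On Primary000106F, 25 of 36 (69.4%, 53.1 to 82.0%) had one, and the diploid list had 39 events there, with a median strength of 49. In so dense a stretch a counterpart within 100 bp can be another site, for example 1548172 for the event at 1548093. The level from random placement over the whole list does not apply there. The haplotig named after the same contig, Haplotig000106F_001, had 35 of its 38 events within 59.4 kb, from 8214 to 67630, with a median strength of 57.8.

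**Figure D2:**
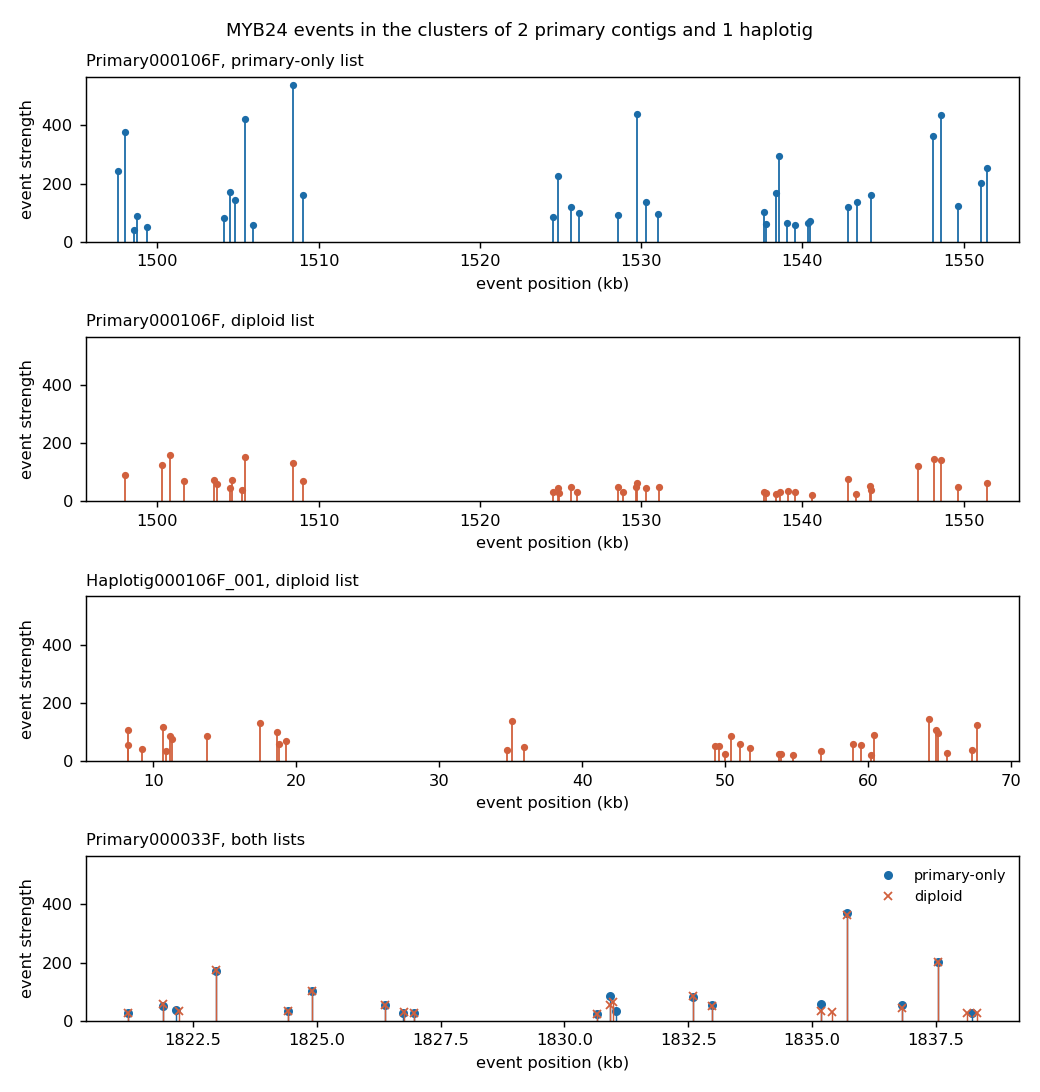
Strength of each MYB24 event (vertical line from 0, in the authors' units) against its position in kb on Primary000106F in the primary-only and the diploid list, on Haplotig000106F_001 in the diploid list, and on Primary000033F in both. The median strength on Primary000106F was 129 in the primary-only and 49 in the diploid list, and 18 of 19 events on Primary000033F were matched.

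Matched positions in the lists were rarely identical. Of the matched primary-only events, 2353 (80.3%) had the diploid event exactly 1 bp away, 1234 of them higher and 1119 lower, and only 4 had it at the same position. Positions from these lists are therefore given to no better than 1 bp.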

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

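Alternatives on clusters, spacing, a common minimum strength and leaving out clusters were chosen after seeing the data. Event numbers followed the threshold by construction: at a −log10 q of at least 5, at least 10 and at or above the median strength, the primary-only list kept 3205, 1541 and 3337 events and the diploid list 2012, 879 and 3123. The share of primary-only events with a counterpart was 38.1% within 20 bp, 45.8% within 500 bp, 40.3% with −log10 q of at least 5 in both lists and 38.7% when diploid events under the primary-only minimum strength were left out. The share of diploid events on primary contigs was 62.9%, 75.3%, 93.0% and 89.3% in the same settings and 74.4% for intervals sharing at least 1 bp. The clusters numbered 29 when linked up to 10 kb and 9 at −log10 q of at least 5, where fewer events enter. The remaining settings left the shares within their intervals, the cluster number within 1.5 times, and the spacing result past its threshold. Motif, gene position and gene list alternatives were not run, since no sequence or gene models of the assembly were used. No paired analysis was possible because each group has 1 library, and no library can be left out.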

Other observations

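Most tests in this part were chosen after the results they bear on were seen. Chosen beforehand were only the comparison of contigs with and without haplotig events, and the permutation test of the share at a multiple among distances elsewhere.

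Some MYB24 events were seen on haplotigs with little on the primary contig of the same name. The 17 haplotigs with events named after Primary000004F held 94 diploid events, against 24 events on Primary000004F in the primary-only list and 8 in the diploid list. The 6 haplotigs with events named after Primary000043F held 35, against 3 and 5. The last primary-only events were at 1104115 on Primary000004F and 670712 on Primary000043F, while haplotig events reached positions 3303784 and 2194464. Contig lengths were not at hand, so these counts are not per length and the stretches compared may differ. In all, 16 primary contigs had more haplotig events than primary-only events, but several of them had 0 primary-only events and only 1 or 2 haplotig events. Primary000277F, with 2 haplotig events, and Primary000394F, with 1, were among these. The counts also come from lists whose smallest strengths differ, 23 for primary-only and 13 for diploid. On Primary000159F, 4 of the 6 distances between the 7 cluster events were 669, 667, 670 and 666 bp.

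In the clusters on Primary000033F and Primary000106F, most distances between neighbouring events lay at multiples of 26 bp. Of 37 distances of up to 1 kb, 25 (67.6%, 51.5 to 80.4%) were within 2 bp of such a multiple, against 17.9% after jittering (permutation p of 1e-05, the smallest 100000 resamples can give, and not corrected for the choice of 26 bp on these same distances). Among all periods from 10 to 150 bp the largest resultant length, 0.678, was at 26 bp (permutation p of 1e-04, corrected over all periods tried and the smallest 10000 can give), and each contig gave 26 bp on its own (p of 0.0162 for Primary000033F, on 12 distances, and 1e-04 for Primary000106F, on 25). On Haplotig000106F_001, 17 of 23 distances (73.9%) were at a multiple (permutation p of 1e-05). This haplotig is named after Primary000106F and its events come from the same library, so it is not an independent repeat of the spacing. In the other 14 clusters of the primary-only list 18 of 43 (41.9%, 28.4 to 56.7%) were at a multiple (permutation p of 3e-04). No period stood out there over all periods tried (largest resultant length 0.348 at 61 bp, permutation p of 0.2916). These 18 were unevenly spread: the 3 clusters on Primary000009F and Primary000211F, singled out after their values were seen, held 12 of 12 and the remaining 11 clusters 6 of 31.

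Technical sources were set against this pattern. A spacing built into the calls would show at close events everywhere, but elsewhere in the list 23.8% of 508 distances (20.3 to 27.7%) were at a multiple, against 19.1% after jittering and 67.6% (51.5 to 80.4%) in the clusters. The bound set beforehand was that the excess elsewhere would not pass its permutation test, and it did pass (p of 0.00481), so that bound was missed; the comparison with the interval of the clusters was given the deciding weight only afterwards. The 12 distances on Primary000009F and Primary000211F are part of this excess, and outside every cluster the share was 22.2% of 465 (18.6 to 26.1%, permutation p of 0.0570). Over all periods tried, the 508 distances elsewhere had their largest resultant length, 0.145, at 148 bp (permutation p of 0.0048). Their value at 26 bp was 0.027. The shares elsewhere therefore argue, by a comparison chosen afterwards, against a spacing built into all close calls as the whole source. A contribution from the calls stays open, and an effect of calling limited to these stretches was not tested. Stacking of reads from both haplotypes on the primary contigs, relieved where haplotigs are included, would weaken the cluster events in the diploid list. On Primary000033F the 18 matched events had a median log2 ratio of diploid to primary-only strength of -0.0034 (95% interval -0.07 to 0.05, exact sign test p of 0.4545). Equal shares of 2 haplotypes would give -1, so no such relief was seen there. Stacking in a stretch without an assembled haplotig would change no ratio and was not tested. Whether an assembled haplotig carries this stretch is not known here, so stacking stays open on Primary000033F. On Primary000106F all 25 ratios were below 0, with a median of -1.58 (-1.99 to -1.27, exact sign test p of 6e-08). Stacking may therefore raise strength there, although some of these pairs can be different sites. The interval lies below -1, so equal shares of 2 haplotypes would not give the whole fall if strength is scaled alike. Over all 2880 matched pairs of the lists the median was -0.041, the 25th percentile -0.89 and the 75th 0. These sign tests and intervals treat neighbouring events of 1 library as independent. The matched share, 78.2% of the 55 cluster events (65.6 to 87.0%), decides nothing, since 54 of them would be above the smallest diploid strength at 0.5 of their own. The spacing was also present in the diploid list, with 68.3% of 41 distances in these stretches at a multiple (permutation p of 1e-05). It is not separate support, since both lists come from 1 library and 43 of the 55 cluster events recur there.

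A high control signal would lower −log10 p at a given strength, and the cluster events were a median of 2.23 above other events of the same strength (permutation p of 1e-04, the smallest 10000 can give), with 9 of 55 below. A tandem repeat of a 26-bp unit, with a bound site in some of its copies, may set the distances; it was not tested against sequence, and no biological role was tested.

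The other pattern is that 3734 primary-only events had no diploid counterpart. Chance at the threshold does not account for it by itself, since only 59.9% (57.3 to 62.5%) of the strongest of the 5 groups by strength had one, under the 80% asked of this explanation. Unmatched events had the lower median −log10 q, 3.96 against 6.46, so chance at the threshold may hold for part of them. Reads of both haplotypes falling on the primary contigs in one list, and being shared with or lost to haplotigs in the other, are a candidate explanation. Among primary contigs with at least 1 primary-only event, on the 259 with no haplotig event a mean of 74.98% of events was matched, against 39.3% on the 168 with haplotig events, a difference of 35.7 percentage points (SD between contigs 35.6 and 19.9, permutation p of 1e-05), and among contigs with at least 10 events the means were 69.2% (19 contigs) and 41% (139 contigs). Neighbouring events shared their status in 65.8% of cases against 57.3% after shuffling within contigs (permutation p of 1e-05). At a −log10 q of 2 to 3 unmatched events had the higher median strength, 34.55 against 29.2, a difference of 5.35 (permutation p of 1e-05). That p-value treats events as independent, although neighbours shared their status. The difference also overlaps with the lower matched share in group 2 by strength (30.4%) than in group 1 (52.5%), so it is not separate support. How reads with 2 equal positions were handled is not given in the sources used here, so loss and sharing of such reads stay open, as do differences between the haplotypes in binding, which the design does not test.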
